A study of Homo sapiens with 8 samples.

How the data were processed

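Total RNA of untreated U251 cells and of U251 cells given forsythoside B was isolated with TRIzol and made into 4 libraries per group with the NEBNext Ultra RNA kit, per the labels. The deposited count table holds whole-number read counts per gene, made by the authors and not normalised, for 62490 gene models. The deposited FPKM table holds FPKM values made by the authors from the same counts. From the values, each FPKM column divides by the gene length and by a library size equal to the DESeq2 size factor times the geometric mean of the 8 totals, not by the column total. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and GRCh38, without saying which step each tool served. The annotation release, the strand setting of the counting and the assembler behind 630 added gene models, 515 of them on patches, alternative haplotypes or other sequences, are not stated. The replicates of a group were kept apart in both tables.

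Depth was 14146189 to 17541132 counts per library. A count of 0 over a group allows up to 3 counts, which is 0.045 CPM in controls and 0.0543 CPM in treated libraries. Counting intervals are exact Clopper-Pearson intervals at 95% on the share of reads in one group, turned into a ratio with the effective library sizes. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Pairs of replicates in a group differed by more than sampling noise, with a chi-square per gene of 4.3 to 29.1 where at least 10 reads were counted.

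Groups were taken from the labels, as 1 factor with 2 levels. Genes were kept with edgeR's filterByExpr, which left 15789 genes, scaled with TMM factors and tested 2-sided with glmQLFit and glmQLFTest (edgeR 4.0.16, R 4.3.3) in a model with the group alone. Benjamini-Hochberg adjustment ran over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the effective library sizes. The common biological coefficient of variation was 0.131. Principal components were taken from log2 CPM of the tested genes.

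A set of 43 gene lists with 1269 entries was fixed before the data were examined, as were the design, the naming rule and the other settings to try. Each list with at least 5 tested genes, 42 in all, was tested with camera (limma 3.58.1) on log2 CPM with the preset inter-gene correlation of 0.01, adjusted over the lists. Beside it ran camera with the correlation estimated per list and fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Lists with fewer tested genes are given as counts. Named genes were the 10 largest rises and 10 largest falls among called protein-coding genes with at least 1 CPM and 10 reads on average in the higher group and no overlap between the groups' libraries, up to 4 members of each described list with the smallest adjusted p, and 18 genes named whatever their change. X-inactivation and Y-linked genes were left out, and some genes that the rule names are not reported here. Genes named outside this rule are marked as looked up after their values were seen.

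The fit was tested on simulated data with the spread of these libraries, in which 200 of 15490 genes were changed. It recovered 62% of genes changed 1.5-fold, 80% at 2-fold, 96% at 4-fold and 98% at 8-fold. Of 175 calls, 7 (4%) were genes left unchanged. Far fewer genes were changed there than the 9180 called in the data, so these rates do not test the scaling at that share.

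The other settings fixed beforehand were DESeq2 size factors, upper-quartile factors, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, no low-count filter, a filter of at least 10 CPM in a group, protein-coding genes only, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5 and on log2(FPKM + 1) for any FPKM above 0, the replicate number as a block, and leaving out each library in turn. Of these, upper-quartile factors, the filter of at least 10 CPM and protein-coding genes only were fixed for the genes, and applied to the gene lists after seeing the data. Further ones, chosen after seeing the data, used only treated replicates 1 and 4, only treated replicates 2 and 3, every library thinned to the smallest total, scaling to total counts, and the added gene models left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.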

Results

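RNA was sequenced from 8 libraries of U251, an established human glioblastoma cell line. The control group held 4 libraries of cells labelled as without special treatment. The other 4 came from cells given 200 µM forsythoside B, a phenylethanoid glycoside found in Forsythia and related plants, and the labels give a time of 48 h. The labels name no solvent and give no time for the controls, and do not say whether the replicates of a group were separate cultures. Every p-value below therefore measures the spread between these libraries only, which may be technical. Control replicates 1 to 4 held 15209594, 16374539, 14693169 and 17541132 counts. Forsythoside B replicates 1 to 4 held 14251263, 14146189, 14391528 and 15192662 counts. Gene levels are given as the mean ± SD of counts-per-million (CPM) over the 4 libraries of a group, control first. Log2 fold changes are forsythoside B relative to control, ± standard error, with edgeR adjusted p-values.

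The single comparison asked how 200 µM forsythoside B altered transcription in U251 cells. Genes of glycolysis and the low-oxygen response rose in 35 of 37 tested members. CA9, a cell-surface carbonic anhydrase, went from 3.52 ± 0.855 to 685 ± 23.4 CPM, and VEGFA, an angiogenic growth factor, from 192 ± 29.3 to 2589 ± 51.2 CPM. All 37 tested genes of the type I interferon list fell, including RSAD2, an antiviral enzyme, from 543 ± 52.4 to 1.77 ± 0.268 CPM. All 49 tested genes of the G1/S list and 59 of 60 of the G2/M list fell, with the proliferation antigen MKI67 going from 550.1 ± 32.6 to 93.4 ± 34.7 CPM. In the metallothionein and zinc list 5 of 6 fell, while 27 of 36 extracellular matrix genes rose. By camera 17 of 42 gene lists shifted, 7 upward and 10 downward, and 1 of them, glycolysis and hypoxia, also did so with an estimated correlation. Of 15789 tested genes, 9180 (58.1%) passed an adjusted p of 0.05, with 4505 higher and 4675 lower, against 9791 at an unadjusted p under 0.05. At least 2-fold changes were found in 3003 genes, 1522 up and 1481 down, and at least 8-fold changes in 136 genes up and 171 down. Protein-coding genes made up 7894 of the calls out of 12443 tested, and of 1995 tested long non-coding RNA genes 414 rose and 363 fell. All 4 libraries of one group lay above all 4 of the other in 8481 tested genes (53.7%), where chance alone gives 2.86%. The first principal component held 74.9% of the variance and parted the groups. The second held 7.93% and spread the treated replicates, from 28.34 in replicate 4 and 23.99 in replicate 1 to -15.39 in replicate 2 and -37.53 in replicate 3. The balance of rises and falls rested on the scaling: 49.1% of called genes were higher with TMM factors, against 37.7% (3531 up and 5832 down) when libraries were scaled to their totals, which moved the median of all genes by -0.13 on the log2 scale.

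**Figure D1:**
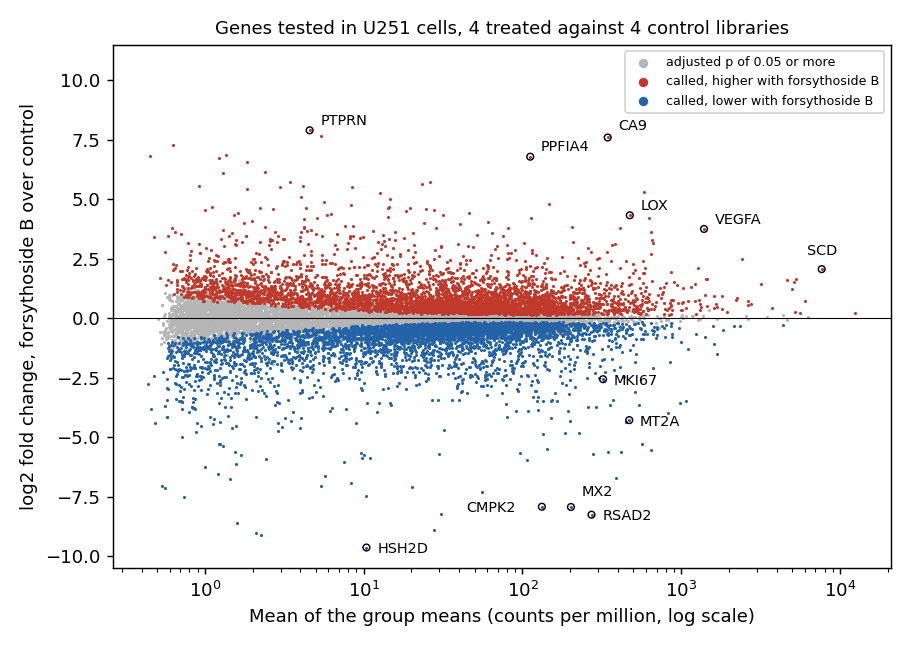
Log2 fold change of each tested gene with forsythoside B (y axis) against its mean level in CPM on a log axis (x axis); each point is a gene, coloured by whether it passed an adjusted p of 0.05. CA9 stands at 7.60 and RSAD2 at -8.25 on the log2 scale, and 9180 of the 15789 points are called.

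Among protein-coding genes that passed the naming rule, the 10 largest rises held CA9 and PPFIA4, which encodes liprin-alpha-4. CA9 (chromosome 9, 35673928 to 35681159, GRCh38) changed by 7.60 ± 0.14 (adjusted p = 5.37e-12). PPFIA4 went from 1.99 ± 0.461 to 222 ± 9.58 CPM, a change of 6.79 ± 0.12 (adjusted p = 5.37e-12). BEND5 went from 0.9199 ± 0.458 to 45.5 ± 3.36 CPM (5.64 ± 0.20), and ZP1 from 0.167 ± 0.14 to 8.14 ± 0.963 CPM (5.55 ± 0.34). Without control replicate 1 the ZP1 value was 6.24. For 5 further genes the controls held 1 to 3 reads in all, so the change is given as a ratio of normalised read sums with a 95% counting interval. PTPRN rose 304-fold (83.8 to 2520) from 2 reads. SEC14L5 rose 238-fold (81 to 1160) from 3 reads, and UPK1A 180-fold (31.8 to 7160) from 1 read. KISS1R, the kisspeptin receptor, rose 86.4-fold (23.5 to 720) from 2 reads. CYGB, the globin cytoglobin, rose 59.8-fold (16.1 to 501) from 2 reads.

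The 10 largest falls were led in level by antiviral genes. RSAD2 (chromosome 2, 6865557 to 6898239, GRCh38) changed by -8.25 ± 0.13 (adjusted p = 3.23e-12). Its neighbour CMPK2, a mitochondrial nucleotide kinase, went from 264 ± 11.6 to 1.08 ± 0.58 CPM (-7.92 ± 0.19). The antiviral GTPase MX2 went from 402 ± 34.6 to 1.64 ± 0.412 CPM (-7.93 ± 0.14), and the chemokine CXCL10 from 61.4 ± 10.7 to 0.2001 ± 0.212 CPM (-8.21 ± 0.29). XAF1, an interferon-induced gene linked to apoptosis, went from 55.6 ± 13.3 to 0.105 ± 0.164 CPM (-8.90 ± 0.38). Leaving out forsythoside B replicate 3 moved CXCL10 to -9.20, and leaving out forsythoside B replicate 4 moved XAF1 to -10.73. SLC15A3, a lysosomal peptide transporter, went from 110.4 ± 3.65 to 0.688 ± 0.0916 CPM (-7.31 ± 0.10, adjusted p = 2.06e-12). HSH2D held 1406 control reads against 1 treated read, 1160-fold lower with an interval of 209 to 46000. FYB1, ZBP1 and TXK had no read in any treated library. Against a floor of 3 counts over the group they were at least 83.6-fold, at least 59-fold and at least 27.1-fold lower, from 4.54, 3.204 and 1.47 CPM. Of these 20 genes, 15 overlap another gene model, 12 of them on the opposite strand. The library kit does not keep strand, so which of 2 overlapping models the reads in a shared stretch came from is uncertain. RSAD2 and CMPK2 share 1079 bp, and both fell. UPK1A shares 5357 bp with its antisense model, which held 2 control and 201 treated reads. The models overlapping FYB1 and TXK held no read, and the one overlapping CXCL10 held 6 control reads and 0 treated reads.

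Glycolysis and hypoxia genes rose in 35 of 37 tested members (also 35 adjusted over the list alone), 32 of them at least 2-fold, with a median log2 change of 2.19. Beside CA9, the mitophagy receptors BNIP3 and BNIP3L went from 95.9 ± 4.71 to 1190 ± 25.2 CPM (3.63 ± 0.065) and from 86.5 ± 1 to 599 ± 41.3 CPM (2.79 ± 0.068). PFKFB4, a regulator of glycolytic flux, went from 58.1 ± 0.58 to 456 ± 21.2 CPM (2.97 ± 0.063). VEGFA changed by 3.76 ± 0.11 (adjusted p = 1.98e-10). The list shifted upward (camera adjusted p = 1.07e-22). It was the only list of 42 that also passed with the correlation between its genes estimated (adjusted p = 0.00227 with an estimated correlation). The 2 members not called, looked up after their values were seen, were PFKM, the muscle phosphofructokinase, with 76.1 ± 5.52 CPM in controls and 72.3 ± 4.65 CPM in treated libraries, and LDHA. LDHA, lactate dehydrogenase A, had 4.54 ± 4.59 CPM in controls and 2.88 ± 2.39 CPM in treated libraries. Its reads in this table were few and varied widely within each group, so neither its level nor the missed call says much about the gene, and the cause of the low counts was not tested. Among housekeeping genes, 6 of 17 rose and 5 fell (6 and 5 adjusted over the list alone). The glycolytic enzymes PGK1 and GAPDH went from 733 ± 28 to 4090 ± 195 CPM and from 2533 ± 97.8 to 7966 ± 492 CPM. TFRC, the transferrin receptor, went from 1038 ± 47.1 to 1572 ± 173 CPM, and YWHAZ from 886 ± 18.1 to 666 ± 30.7 CPM. The housekeeping list did not pass (camera adjusted p = 0.567). Its median was -0.09 while its mean of 0.20 and the camera direction were upward.

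Type I interferon response genes fell in 37 of 37 tested members (37 adjusted over the list alone), 36 of them at least 2-fold, with a median log2 change of -3.90. OASL and IFIT2, both antiviral effectors, went from 209 ± 25.6 to 3.39 ± 0.61 CPM (-5.95 ± 0.14) and from 358 ± 46.2 to 12.6 ± 1.04 CPM (-4.82 ± 0.11), with RSAD2 and MX2 as above. The shift passed (camera adjusted p = 1.66e-23) but not once the correlation between genes was estimated (adjusted p = 0.249 with an estimated correlation). Antigen presentation genes fell in 8 of 9 tested members (8 adjusted over the list alone). NLRC5, the activator of class I genes, went from 216 ± 19.3 to 25.8 ± 3.28 CPM and the peptide transporter TAP2 from 11.9 ± 2.31 to 0.854 ± 0.327 CPM. The trimming peptidases ERAP2 and ERAP1 went from 141 ± 8.99 to 49.3 ± 6.46 CPM and from 77.5 ± 8.16 to 37.1 ± 3.97 CPM. The antigen presentation list shifted downward (camera adjusted p = 0.000621, and adjusted p = 0.106 with an estimated correlation). That list has 19 members, most of the untested ones in the major histocompatibility region. The table holds almost no reads there, so most class I and II genes could not be compared. In the list of NF-kB inflammatory genes 11 of 29 fell and 4 rose (11 and 4 adjusted over the list alone). The adhesion molecule VCAM1 went from 4.8 ± 0.587 to 0.0736 ± 0.06 CPM, and the chemokine CCL2 from 54.8 ± 4.94 to 12.7 ± 3.42 CPM. TNFAIP2 went from 204 ± 15.2 to 112 ± 4.65 CPM and the NF-kB inhibitor NFKBIA from 77.8 ± 6.94 to 34.8 ± 5.41 CPM. The mean log2 CPM over the list was 3.252, 3.868, 4.423 and 3.17 in treated replicates 1 to 4. Controls stood at 4.28 to 4.359, so the list mean did not fall in replicate 3. VCAM1, CCL2, TNFAIP2 and NFKBIA each lay below every control in that replicate too, with CCL2 at 12.1 CPM against 50.5 to 61.6 CPM. The list missed the threshold (camera adjusted p = 0.05). It passed without any 1 of the 4 controls (adjusted p = 0.0369, 0.0488, 0.0482 and 0.0419 for replicates 1 to 4). It also passed without forsythoside B replicate 2 (0.0177) or without forsythoside B replicate 3 (0.00142). Its call depended on the scaling and the filter as well, since it passed with DESeq2 size factors (0.0451), upper-quartile factors (0.0488) or no low-count filter (0.00347), and missed with at least 10 CPM in a group (0.254) or scaling to total counts (0.098).

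Genes of G1/S and DNA replication fell in 49 of 49 tested members (49 adjusted over the list alone), 47 of them at least 2-fold. Genes of G2/M and mitosis fell in 59 of 60 (59 adjusted over the list alone). The replication factors MCM3, ORC6 and PCNA went from 202 ± 14.7 to 39.1 ± 2.95 CPM (-2.37 ± 0.079), from 79.3 ± 5.87 to 14.3 ± 1.17 CPM and from 143 ± 16.2 to 33.5 ± 2.21 CPM. UHRF1, which maintains DNA methylation, went from 108 ± 13.5 to 11.7 ± 1.47 CPM. The mitotic genes MELK and TPX2 went from 222 ± 9.38 to 55.2 ± 7.33 CPM and from 343 ± 18.1 to 56.7 ± 10.5 CPM (-2.60 ± 0.12). SGO1 and CDC25C went from 30.9 ± 2.06 to 5.597 ± 0.835 CPM and from 29.1 ± 2.82 to 4.38 ± 0.716 CPM, and MKI67 changed by -2.56 ± 0.22 (adjusted p = 1.17e-06). The one mitotic member not called, looked up afterwards, was BUB3, a checkpoint protein, with 204 ± 8.57 CPM in controls and 183 ± 18.9 CPM in treated libraries. The median log2 change was -1.89 for G1/S (camera adjusted p = 1.66e-23, and adjusted p = 0.249 with an estimated correlation). For G2/M it was -2.41 (camera adjusted p = 2.09e-25, and adjusted p = 0.27 with an estimated correlation). DNA damage response and repair genes fell in 28 of 34 and rose in 2 (28 and 2 adjusted over the list alone). Among the falls, XRCC2 went from 42.4 ± 2.26 to 8.27 ± 0.751 CPM and RPA2 from 64.1 ± 3.12 to 29.5 ± 0.959 CPM. NBN went from 96.9 ± 5.37 to 34.9 ± 4.14 CPM and LIG1 from 88.6 ± 6.86 to 23.8 ± 4.33 CPM. The DNA repair list shifted downward (camera adjusted p = 1.31e-08, and adjusted p = 0.249 with an estimated correlation). Ribosome biogenesis and MYC target genes fell in 26 of 34 and rose in 2 (26 and 2 adjusted over the list alone). The chaperonin HSPD1 went from 562 ± 28.4 to 244 ± 10.9 CPM. The nucleolar protein genes DKC1, NOP56 and LYAR went from 109.9 to 45.3 CPM, 94.8 to 34.1 CPM and 23.3 to 7.699 CPM. The ribosome biogenesis list shifted downward (camera adjusted p = 1.68e-07, and adjusted p = 0.249 with an estimated correlation). MYC itself went from 26.6 ± 5.18 to 11.4 ± 5.7 CPM (-1.22 ± 0.27, adjusted p = 0.00213). Replication-dependent histone genes fell in 6 of 10 (6 adjusted over the list alone; camera adjusted p = 0.0675, or 0.0451 with no low-count filter). H2BC12 went from 15.9 ± 1.96 to 8.82 ± 0.801 CPM, and H2AC20, H2BC9 and H2BC11 from 1.699 to 0.201 CPM, 1.54 to 0.364 CPM and 1.997 to 0.791 CPM. CCND1, cyclin D1, had 115 ± 16.4 CPM in controls and 85.3 ± 32.5 CPM in treated libraries (adjusted p = 0.0979). Without forsythoside B replicate 3 it was called at -0.71 (adjusted p = 0.000406).

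**Figure D2:**
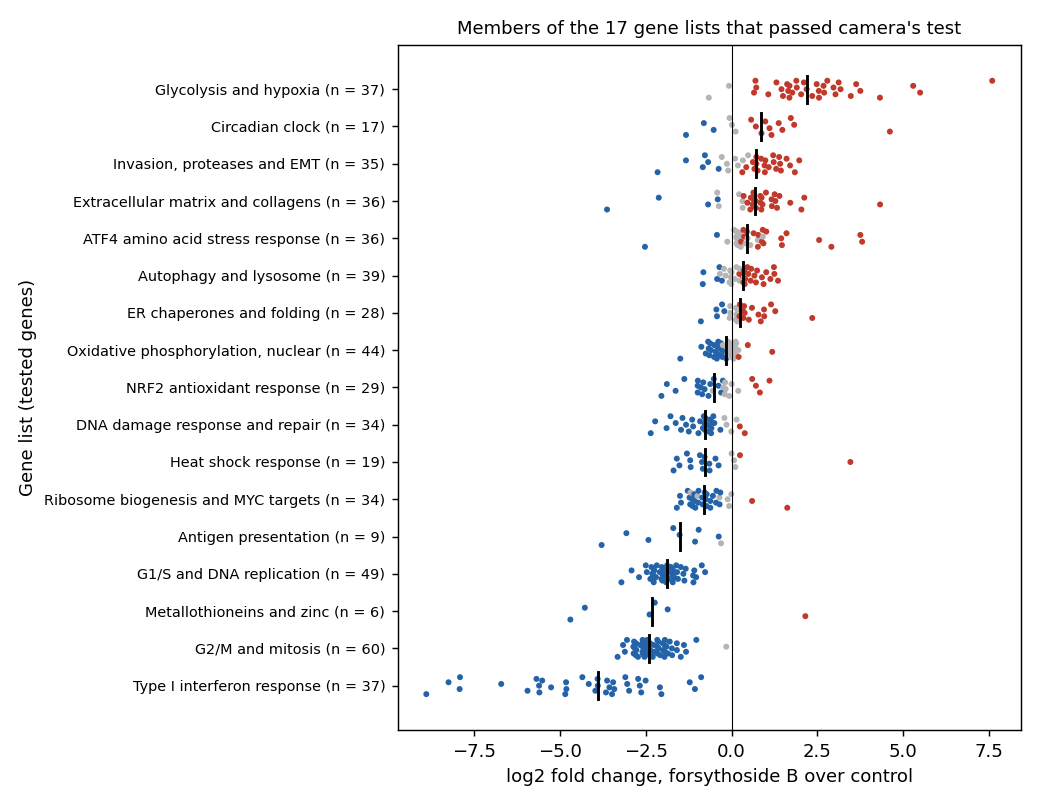
Log2 fold changes (x axis) of the tested members of the 17 gene lists that passed camera's test (y axis). Points are genes, red where called higher, blue where called lower and grey where not called, and the black bar is the list's median. The interferon list has its median at -3.90 and the glycolysis and hypoxia list at 2.19.

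In the list of metallothioneins and zinc genes, 5 of 6 tested members fell and 1 rose (5 and 1 adjusted over the list alone). The metal-binding proteins MT2A and MT1E went from 895 ± 105 to 46.2 ± 6.11 CPM (-4.28 ± 0.12) and from 61.6 ± 1.27 to 2.35 ± 1.36 CPM (-4.70 ± 0.26). The zinc exporter SLC30A1 fell from 79.5 ± 5.87 to 15.2 ± 0.67 CPM (-2.39 ± 0.078), and the zinc importer SLC39A10 rose from 45.2 ± 1.24 to 201 ± 22.9 CPM (2.15 ± 0.086). The list passed (camera adjusted p = 0.0115, and adjusted p = 0.249 with an estimated correlation). Reads of metallothionein copies can be shared between paralogs. NRF2 antioxidant genes fell in 17 of 29 and rose in 4 (18 and 4 adjusted over the list alone). Thioredoxin TXN went from 196 ± 9.39 to 114 ± 9.55 CPM and glutathione reductase GSR from 173 ± 4.46 to 92.6 ± 11.6 CPM. The quinone reductase NQO1 went from 563 ± 18.1 to 318 ± 43.6 CPM (-0.82 ± 0.090) and UGDH from 57.4 ± 2.78 to 37.4 ± 2 CPM. The NRF2 list shifted downward (camera adjusted p = 0.00468, and adjusted p = 0.569 with an estimated correlation). Its mean log2 CPM was 6.161, 6.478, 6.744 and 6.08 in treated replicates 1 to 4, against 6.854 to 6.933 in controls. With only treated replicates 2 and 3, a fit chosen after seeing the data, the call was lost (adjusted p = 0.0539). HMOX1, heme oxygenase, was called as a rise, from 71 ± 12.1 to 153 ± 119 CPM (1.11 ± 0.44, adjusted p = 0.0475). Its treated replicates 1 to 4 stood at 70.7, 176, 312 and 53.6 CPM. The HMOX1 call was lost without any 1 of the 4 controls (log2 changes 1.10, 1.08, 1.03 and 1.22 for replicates 1 to 4). It was also lost without forsythoside B replicate 2 (1.04) and without forsythoside B replicate 3 (0.50, adjusted p = 0.187). In the ferroptosis and iron list 10 of 26 rose and 7 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.562). In it FANCD2, GCH1 and LPCAT3 fell from 78.2 to 31.2 CPM, 19.7 to 6.79 CPM and 15.5 to 7.63 CPM. Heat shock genes fell in 14 of 19 and rose in 2 (14 and 2 adjusted over the list alone). The chaperone genes HSP90AA1, HSPH1 and DNAJA1 went from 1557 ± 112 to 632 ± 27.7 CPM, from 229.5 ± 11.1 to 76 ± 5.54 CPM and from 498 ± 28.4 to 154 ± 13.8 CPM. The heat shock list shifted downward (camera adjusted p = 0.000375, and adjusted p = 0.249 with an estimated correlation). The 2 risers, named after their values were seen, were the small heat shock protein CRYAB, from 0.892 ± 0.526 to 9.98 ± 2.03 CPM, and the co-chaperone BAG3, from 126 ± 10.1 to 149 ± 3.21 CPM.

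ATF4 stress genes rose in 18 of 36 and fell in 2 (18 and 2 adjusted over the list alone), with a median of 0.46. The mTORC1 inhibitor DDIT4 went from 54.5 ± 6.91 to 763 ± 103 CPM (3.81 ± 0.12) and CHAC1 from 15.8 ± 2.1 to 119 ± 18.1 CPM (2.91 ± 0.13). CHAC1, a glutathione-degrading enzyme, is also in the ferroptosis list. The lipoprotein receptor VLDLR went from 121 ± 6.77 to 366 ± 14.2 CPM, alongside VEGFA, which the hypoxia list also holds. The ATF4 list shifted upward (camera adjusted p = 0.000802, and adjusted p = 0.599 with an estimated correlation). The rise of the list mean lay mostly in treated replicates 2 and 3. That mean was 6.752, 7.319, 7.648 and 6.816 log2 CPM in treated replicates 1 to 4, against 6.228 to 6.587 in controls. With only treated replicates 1 and 4, a fit chosen after seeing the data, the call was lost (adjusted p = 0.235). The stress transcription factors DDIT3 and ATF3 were not called. DDIT3 had 42.9 ± 6.17 CPM in controls and 50.8 ± 28.3 CPM in treated libraries (adjusted p = 0.525), and ATF3 had 26.9 ± 3.8 CPM in controls and 45.9 ± 33.9 CPM in treated libraries (adjusted p = 0.13). DDIT3 had a log2 change of 0.24 ± 0.31, which was -0.16 without forsythoside B replicate 3. ATF3 had 0.77 ± 0.41 and was called without forsythoside B replicate 1 (1.04, adjusted p = 0.0265) or without forsythoside B replicate 4 (1.02, adjusted p = 0.0362). ER chaperone and folding genes rose in 15 of 28 and fell in 5 (15 and 5 adjusted over the list alone). The oxidase ERO1A went from 82.2 ± 2.86 to 420.2 ± 60.2 CPM. The disulfide isomerases PDIA3 and P4HB went from 368 ± 8.16 to 817 ± 38.3 CPM and from 1237 ± 64.4 to 2395 ± 116 CPM, and EDEM1 from 132 ± 3.52 to 319.7 ± 39.6 CPM. The ER chaperone list shifted upward (camera adjusted p = 0.0238, and adjusted p = 0.399 with an estimated correlation). Autophagy and lysosome genes rose in 21 of 39 and fell in 5 (21 and 5 adjusted over the list alone). Prosaposin PSAP went from 2930 ± 149 to 6961 ± 107 CPM and ATG9A from 76.7 ± 2.98 to 168 ± 8.7 CPM. MAP1LC3A went from 25.4 ± 2.65 to 64.9 ± 2.85 CPM and the hexosaminidase HEXA from 49.5 ± 6.3 to 117 ± 8.68 CPM. The autophagy and lysosome list shifted upward (camera adjusted p = 0.00528, and adjusted p = 0.548 with an estimated correlation). Its mean log2 CPM was 6.605, 6.832, 6.825 and 6.603 in treated replicates 1 to 4, against 6.38 to 6.438 in controls, and the call was lost with only treated replicates 1 and 4 (adjusted p = 0.0667).

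Extracellular matrix genes rose in 27 of 36 and fell in 4 (28 and 5 adjusted over the list alone), with a median of 0.68. The collagen cross-linking enzymes LOX and PLOD2 went from 44.9 ± 3.48 to 903 ± 82.1 CPM (4.33 ± 0.092) and from 201 ± 2.23 to 824 ± 55.2 CPM. Fibronectin FN1 rose from 476 ± 46.4 to 2073 ± 214 CPM (2.12 ± 0.094), and the collagen chain COL6A3 fell from 27.6 ± 1.06 to 2.22 ± 0.44 CPM (-3.63 ± 0.13). The matrix list shifted upward (camera adjusted p = 1.41e-06, and adjusted p = 0.249 with an estimated correlation). Genes of invasion, proteases and the epithelial-mesenchymal transition rose in 22 of 35 and fell in 6 (23 and 7 adjusted over the list alone). The matrix metalloproteinase MMP2 went from 146 ± 3.78 to 524 ± 36.7 CPM (1.85 ± 0.067), and the integrin ITGB5 from 104 ± 4.34 to 317 ± 16.8 CPM. ADAMTS1 went from 32.6 ± 0.573 to 128 ± 13 CPM and MMP17 from 12.3 ± 0.885 to 40.01 ± 2.57 CPM. The invasion list shifted upward (camera adjusted p = 0.000155, and adjusted p = 0.0608 with an estimated correlation). MMP9 had 4 control reads and 1 treated read and was not tested. TGF-beta targets rose in 14 of 27 and fell in 7 (14 and 8 adjusted over the list alone; camera adjusted p = 0.0675). That list passed with at least 10 CPM in a group (adjusted p = 0.0223) or with no low-count filter (0.00355). Here IGFBP3 rose from 4.07 ± 0.716 to 87.7 ± 7.04 CPM, and ID2 fell from 22.1 ± 1.63 to 4.84 ± 0.542 CPM. Senescence secretome genes rose in 12 of 25 and fell in 7 (12 and 7 adjusted over the list alone; camera adjusted p = 0.0875, or 0.0138 with no low-count filter). Their mean log2 CPM was 5.731, 6.031, 6.166 and 5.682 in treated replicates 1 to 4, against 5.321 to 5.385 in controls. The hormone STC1 went from 62.9 ± 2.54 to 1183 ± 64.8 CPM (4.23 ± 0.071) and IGFBP5 from 135 ± 6.48 to 1191 ± 324 CPM. Among YAP and TEAD targets 13 of 25 fell and 6 rose (13 and 6 adjusted over the list alone; camera adjusted p = 0.162, or 0.0394 with no low-count filter). Among these NT5E and AMOTL2 fell from 163 to 56.4 CPM and 88.6 to 38.1 CPM, and PTPN14 rose from 92.2 to 212 CPM.

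Glial and neural stem markers rose in 11 of 19 and fell in 4 (11 and 4 adjusted over the list alone). VIM, CD44 and FABP7 rose from 1699 ± 82.9 to 4611 ± 677 CPM, from 947 ± 17.9 to 1876 ± 205 CPM and from 22.4 ± 0.996 to 62.3 ± 8.5 CPM. The astrocyte filament GFAP rose from 120.2 ± 16.1 to 334 ± 190 CPM (1.47 ± 0.33, adjusted p = 0.00253). ALDH1L1, an astrocyte folate enzyme, fell from 6.097 ± 0.838 to 0.328 ± 0.1 CPM. The mean log2 CPM over the list was 6.041, 5.621, 5.49 and 6.092 in treated replicates 1 to 4. Controls stood at 5.539 to 5.588, so the rise of the list mean lay mostly in replicates 1 and 4. VIM, CD44, FABP7 and GFAP stood above every control in replicates 2 and 3 as well. GFAP stood at 449.9, 176.9, 166.7 and 540.5 CPM in treated replicates 1 to 4. The list missed the threshold (camera adjusted p = 0.0675). It passed without forsythoside B replicate 2 (adjusted p = 0.0379) or replicate 3 (0.0162), with at least 10 CPM in a group (0.0477) or with no low-count filter (0.0251). The stem cell factor SOX2 went from 289.9 ± 10.2 to 445 ± 106 CPM (0.62 ± 0.14). Nestin, NES, was not called at 245 ± 9.5 CPM in controls and 275 ± 49 CPM in treated libraries (adjusted p = 0.218), but was without forsythoside B replicate 2 (0.27, adjusted p = 0.0308). Neuron markers rose in 6 of 8 and fell in 1 (6 and 1 adjusted over the list alone). GAD1 went from 14.5 ± 1.32 to 55.3 ± 6.69 CPM and SLC17A7 from 0.641 ± 0.15 to 8.62 ± 2.25 CPM. MAP2 rose from 96.5 ± 8.87 to 169 ± 28 CPM and NEFL fell from 1058 ± 109 to 680 ± 35.3 CPM. That list also missed the threshold (camera adjusted p = 0.0509). It passed without control replicates 1 (0.0382), 2 (0.0424) or 4 (0.0478) or forsythoside B replicates 3 (0.042) or 4 (0.0467). Glioma receptor and PI3K pathway genes rose in 12 of 36 and fell in 11 (12 and 11 adjusted over the list alone; camera adjusted p = 0.571). The growth factors TGFA, PDGFB and PDGFA rose from 20.8 ± 3.26 to 98.1 ± 6.78 CPM, from 5.17 ± 0.795 to 25.2 ± 9.45 CPM and from 12.5 ± 1.16 to 24.3 ± 1.49 CPM. The receptor EGFR rose from 181 ± 5.7 to 252 ± 29.5 CPM (0.48 ± 0.082).

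Among BCL2 family and caspase genes 13 of 29 fell and 6 rose (14 and 6 adjusted over the list alone; camera adjusted p = 0.0985, or 0.0239 with no low-count filter). BIRC5, survivin, which is also a mitotic protein, fell from 143 ± 12.4 to 24.3 ± 6.42 CPM. CASP2 fell from 73.7 ± 4.41 to 36.5 ± 1.42 CPM, and the survival gene BCL2L2 rose from 37.7 ± 3.53 to 60.7 ± 1.56 CPM. BCL2 fell from 5.26 ± 0.645 to 2.39 ± 0.262 CPM (-1.14 ± 0.18). BAX fell from 111 ± 7.72 to 72.8 ± 13.3 CPM (-0.61 ± 0.12). Among p53 targets 12 of 28 fell and 7 rose (12 and 7 adjusted over the list alone; camera adjusted p = 0.236). PLK2 and FAS fell from 183 ± 23.4 to 33.8 ± 2.71 CPM and from 29.4 ± 2.15 to 9.83 ± 1.23 CPM, and ZMAT3 and TP53INP1 rose from 37.3 to 72.03 CPM and 24.2 to 47.6 CPM. CDKN1A, the p21 cell cycle inhibitor, was not called, at 166 ± 12.3 CPM in controls and 186 ± 54.8 CPM in treated libraries (0.17 ± 0.16, adjusted p = 0.408). Its log2 change was -0.04 without forsythoside B replicate 3.

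**Figure D3:**
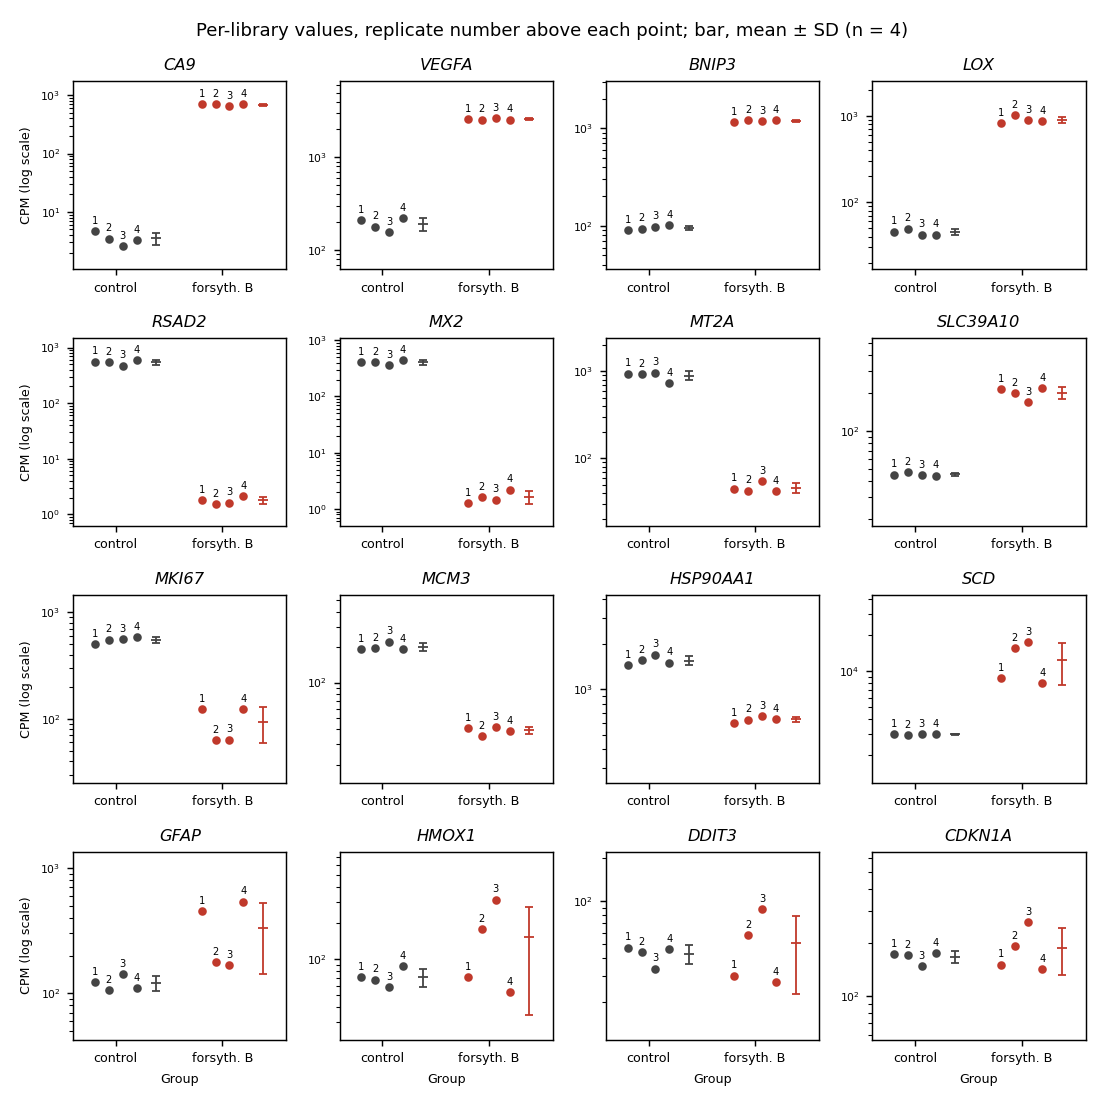
Levels per library of genes the text names, in CPM on a log axis (y axis), with points for the 4 control and 4 forsythoside B libraries and bars for the group mean and SD. CA9, VEGFA and BNIP3 are higher and RSAD2, MKI67 and MT2A lower in all 4 treated libraries, while HMOX1 spans 53.6 to 312 CPM within the treated group.

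Nuclear genes of oxidative phosphorylation fell in 22 of 44 and rose in 3 (22 and 3 adjusted over the list alone). ATP5F1B went from 710.2 ± 15.1 to 448 ± 19 CPM and CYC1 from 113 ± 2.91 to 70.2 ± 7.59 CPM. ATP5MC3 went from 191 ± 9.18 to 113 ± 14.6 CPM and UQCRFS1 from 137 ± 11.7 to 88.9 ± 4.21 CPM. The oxidative phosphorylation list shifted downward (camera adjusted p = 0.0238, and adjusted p = 0.548 with an estimated correlation). That list missed the threshold without forsythoside B replicate 2 (adjusted p = 0.0513), among protein-coding genes only (0.0503) and with only treated replicates 1 and 4 (0.0928). Transcripts of the mitochondrial genome rose in 4 of 13 and fell in 3 (4 and 3 adjusted over the list alone; camera adjusted p = 0.575). MT-CYB fell from 2144 ± 76.3 to 1543 ± 108 CPM and MT-CO2 rose from 4695 ± 212 to 5667 ± 408 CPM. MT-ND2 and MT-ATP8 fell from 1759 to 1422 CPM and 28.2 to 12.6 CPM. Cholesterol synthesis genes fell in 12 of 24 and rose in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0675). NSDHL and FDFT1 fell from 43.6 to 23.95 CPM and 36.1 to 18.1 CPM, and TM7SF2 rose from 32.6 to 52.7 CPM. Their mean log2 CPM was 5.692, 6.092, 6.461 and 5.648 in treated replicates 1 to 4, against 6.226 to 6.502 in controls, with replicate 3 inside the control range. The cholesterol list passed without control replicate 2 (adjusted p = 0.0488) or without forsythoside B replicate 3 (0.00372). It also passed with the replicate number as a block (0.0332), as the single list gained there, or with no low-count filter (0.00383). Fatty acid synthesis genes fell in 4 of 16 and rose in 3 (3 and 3 adjusted over the list alone; camera adjusted p = 0.723), with a mean log2 CPM of 7.186, 7.375, 7.656 and 7.104 in treated replicates 1 to 4, against 7.274 to 7.426 in controls. The desaturase SCD rose from 2949 ± 28.6 to 12370 ± 4760 CPM. The elongase ELOVL5 and ligase ACSL3 fell from 685 ± 24.9 to 312 ± 17.2 CPM and from 266 ± 3.86 to 127 ± 23.4 CPM, while AGPAT2 rose from 33.9 to 59.6 CPM. Ribosomal protein genes fell in 20 of 71 and rose in 13 (20 and 12 adjusted over the list alone; camera adjusted p = 0.644). RPS23 and RPS26 fell from 144 to 84.6 CPM and 93.7 to 48.2 CPM, and RPL3 and RPL4 rose from 527 to 789.7 CPM and 559 to 811 CPM. AHR targets rose in 3 of 9 and fell in 4 (4 and 4 adjusted over the list alone; camera adjusted p = 0.948). STC2 and SLC7A5 rose from 23.8 to 140 CPM and 306 to 849 CPM, and CYP1B1, a direct target, fell from 3.27 to 0.655 CPM. Xenobiotic genes fell in 8 of 20 and rose in 4 (8 and 4 adjusted over the list alone; camera adjusted p = 0.332). CYP2J2 and ABCC2 fell from 23.5 to 6.28 CPM and 29.1 to 11.2 CPM, and GSTM3 and ABCC3 rose from 42.4 to 73.2 CPM and 106 to 188 CPM.

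Circadian clock genes rose in 11 of 17 and fell in 3 (11 and 3 adjusted over the list alone). The nuclear receptor RORA went from 1.55 ± 0.312 to 37.8 ± 10.6 CPM (4.62 ± 0.24) and PER1 from 26.4 ± 2.3 to 73.6 ± 6.76 CPM. NPAS2 went from 6.97 ± 0.368 to 24.7 ± 2.99 CPM and BHLHE41 from 48.5 ± 5.39 to 161 ± 25.7 CPM. The circadian list shifted upward (camera adjusted p = 0.00811, and adjusted p = 0.249 with an estimated correlation). Immediate early and AP-1 genes rose in 7 of 25 and fell in 3 (7 and 3 adjusted over the list alone; camera adjusted p = 0.203). Their mean log2 CPM was 4.248, 4.633, 4.944 and 4.23 in treated replicates 1 to 4, against 4.018 to 4.216 in controls. FOSL2 and JUN rose from 149 ± 7.92 to 391.6 ± 15.9 CPM and from 216 ± 13.4 to 551 ± 16.7 CPM, and NR4A1 and DUSP1 from 6.52 to 20.2 CPM and 20.2 to 81.5 CPM. ERK feedback genes rose in 8 of 19 and fell in 4 (8 and 4 adjusted over the list alone; camera adjusted p = 0.228), with a mean log2 CPM of 5.032, 5.286, 5.61 and 5.098 in treated replicates 1 to 4, against 5.044 to 5.157 in controls. PHLDA1 rose from 259.7 to 706 CPM, and SPRY1, SPRED1 and SPRED3 from 6.34 to 22.5 CPM, 61.5 to 93.2 CPM and 11.8 to 22.4 CPM. Notch pathway genes rose in 5 of 13 and fell in 4 (5 and 4 adjusted over the list alone; camera adjusted p = 0.571). HEY1, JAG2, LFNG and JAG1 rose from 18.3 to 52.99 CPM, 3.64 to 17.5 CPM, 4.05 to 20.5 CPM and 74.1 to 120.4 CPM. The median of that list was -0.29 while its mean of 0.30 and the camera direction were upward. Wnt targets rose in 6 of 16 and fell in 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.468). TNFRSF19, DKK1 and SFRP1 rose from 4.01 to 14.3 CPM, 346 to 461 CPM and 39.8 to 53.7 CPM, and APCDD1 fell from 5.43 to 2.34 CPM.

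Markers of other cell types were mostly at low levels. Of 21 blood and immune cell markers, 3 could be tested and 1 rose (1 adjusted over the list alone), CD4, from 0.481 ± 0.176 to 1.08 ± 0.397 CPM (adjusted p = 0.0245). The CD4 call was lost without control replicates 1 (1.05, adjusted p = 0.0674) or 2 (0.97, 0.0756) and without forsythoside B replicates 1 (1.06, 0.0662) or 4 (1.03, 0.0715). Endothelial markers rose in 2 of 6 and fell in 1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.468). EGFL7 and CDH5 rose from 3.997 ± 0.213 to 13.95 ± 0.726 CPM and from 0.773 ± 0.255 to 9.18 ± 3.46 CPM, and KDR fell from 15.7 ± 1.14 to 9.22 ± 1.23 CPM. Epithelial markers fell in 3 of 8 and rose in 1 (3 and 1 adjusted over the list alone; camera adjusted p = 0.279). KRT18, ELF3 and AFP fell from 25.8 to 17.5 CPM, 5.903 to 2.21 CPM and 2.41 to 0.803 CPM, and MUC1 rose from 7.55 ± 1.12 to 25.7 ± 5.57 CPM. Nuclear and intronic RNA rose in 5 of 10 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0675, or 0.00455 with no low-count filter). MEG3, OIP5-AS1, SNHG14 and NORAD rose from 41.2 to 88.8 CPM, 110 to 202 CPM, 114 to 194 CPM and 431 to 563 CPM. The nuclear RNA list passed without control replicate 1 (adjusted p = 0.0459). RNA composition moved with treatment. Mitochondrial ribosomal RNA took 0.318 ± 0.0171% of control counts and 0.797 ± 0.0382% of treated counts. The 10 most abundant genes took 5.48 ± 0.177% and 7.71 ± 0.362%. Messenger RNA of the mitochondrial genome took 3.79 ± 0.16% and 3.69 ± 0.207%.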

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

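The screen for libraries far from the rest of their group was set before the values were seen, and no test of a cause was run here. For each named gene reported here, list mean and library measure, the gap between the highest or lowest library and its nearest neighbour was divided by the range of the 4 libraries of the group. A result is given where this share passed Dixon's 95% critical value for 4 samples. That happened in 24 of 461 groups of values, where chance gives about 1 in 20, or 23, so the number is close to what chance alone would give. No biological explanation was tested for any of them, since the labels tell the replicates of a group apart by number alone.

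Control replicate 3 held 6 of the 24. Its mean log2 CPM over G1/S and DNA replication genes was 5.811, against 5.624 to 5.634 in the other controls (share 0.947). Its MCM3 level was 224 CPM against 193 to 198 (0.8291), and its COL6A3 level 26.0 CPM against 28.0 to 28.3 (0.885). SLC7A5 stood at 245 CPM against 322 to 336 (0.854), KRT18 at 27.5 CPM against 25.1 to 25.4 (0.874), and CDKN1A at 148 CPM against 169 to 174 (0.832).

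In control replicate 4, PER1 was at 22.9 CPM against 27.0 to 27.8 (0.83), and ERAP1 at 89.6 CPM against 72.1 to 74.8 (0.846). GCH1 was at 22.7 CPM against 18.3 to 19.0 (0.857), and PDGFB at 3.98 CPM against 5.47 to 5.62 (0.909). In control replicate 1, EDEM1 was at 137 CPM against 130.1 to 131 (0.905). In control replicate 2, NES was at 231 CPM against 249.5 to 250.9 (0.934).

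Forsythoside B replicate 3 held 6. CA9 was at 649.7 CPM against 694 to 698 (0.928), TXN at 128 CPM against 108 to 109.9 (0.897), RPS23 at 94.8 CPM against 80.6 to 82.1 (0.893), and FDFT1 at 24.6 CPM against 15.3 to 16.3 (0.892). Its mean log2 CPM was 5.353 against 5.149 to 5.181 over ribosome biogenesis and MYC target genes (0.843), and 6.216 against 6.161 to 6.167 over glioma receptor and PI3K pathway genes (0.891). In forsythoside B replicate 4, STC1 was at 1279 CPM against 1141 to 1158 (0.878), NLRC5 at 30.7 CPM against 23.8 to 24.6 (0.889), NORAD at 619 CPM against 539 to 549 (0.874), and the mean log2 CPM of mitochondrial genome transcripts at 10.50 against 10.32 to 10.34 (0.889). In forsythoside B replicate 2, KRT18 was at 20.9 CPM against 16.2 to 16.5 (0.942), and the mean log2 CPM of nuclear and intronic RNA at 7.084 against 6.751 to 6.801 (0.85). For CA9, STC1, NLRC5, MCM3 and COL6A3 these gaps were smaller than the difference between the group means.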

How the results depend on the processing

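The alternatives using only treated replicates 1 and 4, only treated replicates 2 and 3, thinned libraries, scaling to total counts and no added gene models were chosen after seeing the data, as were upper-quartile factors, the filter of at least 10 CPM in a group and protein-coding genes only for the gene lists; the others were planned. Across all of them 7130 to 9794 genes were called, and 8584 to 9454 when 1 library was left out. No gene called both in an alternative and in the reported fit had opposite directions. Of 4539 comparisons of a named gene with an alternative, 4492 kept direction and call, 26 lost the call, 14 gained it and 7 reversed, and 180 of the 191 named genes kept both throughout. With 3003 genes changed at least 2-fold in the reported fit, the count was 1666 with a filter of at least 10 CPM in a group, where fewer genes were tested. It was 1505 and 1475 on log2(FPKM + 1), with and without a minimum FPKM, where the added 1 shrinks the folds of low values. Against 17 lists, 26 passed with no low-count filter and 36 with fry, which compares a list with no change rather than with other genes. With camera on an estimated correlation 1 passed. The antigen presentation, invasion and metallothionein lists lost their call there with estimates of -0.01, -0.00518 and -0.0654. These lie below the preset 0.01, so a higher correlation was not the reason for those lists. The glycolysis and hypoxia list had an estimate of 0.00954, near the preset, yet its unadjusted camera p went from 1.01e-23 to 5.42e-05. Estimating the correlation thus weakened the test even where the correlation hardly differed from the preset. A call lost there does not by itself mean that correlation explains the shift. For the unfiltered count the cause was not tested, nor was the part of correlation in the other lost lists. With only treated replicates 1 and 4, HMOX1 had a log2 change of -0.19, ATF3 -0.44, DDIT3 -0.58 and CDKN1A -0.18, and 3 lists lost their call: nuclear oxidative phosphorylation (adjusted p = 0.0928), ATF4 (0.235) and autophagy (0.0667), while the cholesterol (3.59e-05), NF-kB (2.96e-06) and glial (0.000924) lists passed. With only treated replicates 2 and 3, NES had -0.052 and the NRF2 list lost its call (0.0539), while the immediate early (0.00474), ERK feedback (0.0477), senescence (0.0111), nuclear RNA (0.0332) and neuron (0.0373) lists passed; fewer treated libraries entered these fits. Leaving out 1 library gave -0.037 to 0.29 for CDKN1A and -0.16 to 0.46 for DDIT3, the lowest without forsythoside B replicate 3; the cause was not tested. Nuclear oxidative phosphorylation also missed the threshold among protein-coding genes only (0.0503). No list that passed changed direction in any alternative. With the replicate number as a block, 8994 genes (4394 up, 4600 down), 2996 at 2-fold and 18 lists passed. The labels do not call the numbers a pairing: correlations of residual levels between control and treated libraries were 0.00667 to 0.0424 for equal numbers and -0.078 to 0.0644 for others, and 3 libraries matched their own number best. Depth limits genes with few reads, whose folds against 1 to 3 reads have intervals spanning more than 10-fold.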

Other observations

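The tests of immune cells, of metallothionein paralogs, of zinc and of all gene sets described here were chosen only after the result was seen. The splits of the libraries, the comparisons with genes of like GC and length, and the tests of interferon ligands and of iron by TFRC were set before. SLC11A2 and CDC42BPA were added to the iron test after the main fit. Enzymes that use oxygen and 2-oxoglutarate rose in 22 of 29 tested members and fell in 2. This set was picked after the hypoxia rise was seen, and members shared with earlier lists, such as PLOD2 of the matrix list, were not removed. Its rise is therefore not evidence separate from those lists. The prolyl hydroxylases EGLN1 and EGLN3, which mark HIF proteins for degradation, rose from 38.3 ± 5.28 to 173 ± 7.75 CPM and from 9.88 ± 0.462 to 80.8 ± 9.75 CPM. The histone demethylases KDM3A and KDM4B rose from 52.4 ± 0.818 to 169 ± 4.25 CPM and from 77.3 ± 3.92 to 243 ± 9.02 CPM, the DNA demethylase TET1 from 4.43 ± 0.978 to 18.2 ± 4.52 CPM, the collagen hydroxylase P4HA1 from 88.4 ± 5.18 to 516 ± 16.5 CPM and the RNA demethylase ALKBH5 from 173 ± 7.96 to 428 ± 18.9 CPM (camera adjusted p = 2.32e-08 over the added sets; adjusted p = 0.0174 with an estimated correlation). Genes of glycogen metabolism rose in 9 of 17 and fell in 3, with glycogen synthase GYS1 from 89.02 ± 6.44 to 496 ± 21.2 CPM and the phosphatase subunit PPP1R3C from 4.82 ± 0.656 to 75.5 ± 9.79 CPM (camera adjusted p = 0.00386; adjusted p = 0.0776 with an estimated correlation). EPAS1, which encodes HIF-2alpha, rose from 54.6 ± 3.7 to 228 ± 6.79 CPM, and HIF1A was not called, at 745 ± 55.1 CPM in controls and 647 ± 72.8 CPM in treated libraries (adjusted p = 0.0638). The cell cycle inhibitors CDKN1B and CDKN1C rose from 85.5 ± 5.22 to 136 ± 6.96 CPM and from 0.309 ± 0.238 to 1.81 ± 0.966 CPM, and HOXA13, a body patterning gene, from 1.41 ± 0.559 to 27.2 ± 2.91 CPM. HOXA13 was the largest riser of its set, in which 2 of 9 tested HOXA genes rose and 3 fell. The HOXA set missed the threshold (camera adjusted p = 0.975).

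Interferon-stimulated genes stood high in the untreated cells. The 37 tested list members had a median of 419 CPM in controls, at the 98.2 percentile of tested genes, and of 24.4 CPM in treated libraries, at the 55.3 percentile, and 32 of them passed 100 CPM in controls against 5 in treated libraries. Nucleic acid sensors fell in 7 of 9 tested members and rose in none (camera adjusted p = 8.7e-06; adjusted p = 0.069 with an estimated correlation), with IFIH1 from 365 ± 20.4 to 24.4 ± 2.96 CPM and TLR3 from 66.04 ± 5.71 to 6.17 ± 0.406 CPM. The receptor IFNAR1 had 80.7 ± 7.24 CPM in controls and 78.03 ± 6.6 CPM in treated libraries and MAVS 191 ± 12.6 CPM in controls and 184 ± 10.2 CPM in treated libraries, neither called. A set of guanylate-binding genes, IFI44, IFI44L and GIMAP2 fell in 8 of 8 tested members, of which paralogs can share reads (camera adjusted p = 8.38e-07, and adjusted p = 0.069 with an estimated correlation). Apolipoprotein L genes fell in 4 of 4. The sensor, guanylate-binding and apolipoprotein L sets were picked after the interferon fall was seen, and any members shared with the interferon list were not removed. Their falls are therefore no separate evidence for it. In the major histocompatibility region of chromosome 6 (29722775 to 33089696) 111 of 136 coding models had no read (81.6%), against 143 of 913 elsewhere on that chromosome (15.7%), and 4 were tested. Treated replicates 1 and 4 lay at least 2-fold apart from replicates 2 and 3 in 91 tested genes, with 0.5 CPM added, against 17 and 19 genes for the other pairings. MTF1, the zinc-sensing activator of metallothioneins, fell from 50.1 ± 4.11 to 42.6 ± 4.64 CPM (adjusted p = 0.0486), and the glucocorticoid targets FKBP5 and TSC22D3 went from 36.8 ± 3.75 to 10.8 ± 1.63 CPM and from 22.3 ± 3.38 to 42.2 ± 16 CPM.

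The number of called genes was set against other divisions of the 8 libraries. Of the 35 splits into 4 and 4, only 1, the real one, called as many as 9180 genes. The highest other split called 1. Every other split placed control and treated libraries together on both sides, so the group difference became spread within each side. Few calls there would follow from any large group difference, so the contrast in counts only restates that the groups differ. The rank of the real split, 1 of 35, is the most extreme this test can give. A difference between single cultures, if the replicates of a group share one, was not tested and stays open.

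The fall of interferon-stimulated genes was weighed against bias, other cells and a loss of ligand. Relative to the 100 tested genes nearest in GC content, length and level, the list's median log2 change was -3.85 (95% bootstrap interval -4.69 to -3.42) against -3.90 before, so such a trend as the whole cause is argued against. Leukocytes in the control cultures are argued against by PTPRC, CD74, TYROBP, FCER1G and LYZ, abundant in those cells, which together reached 0.988 CPM in the highest control library. Interferon ligand genes summed to 2.27 CPM in controls and 1.61 CPM in treated libraries, a log2 ratio of -0.498 ± 0.168, with IFNB1 at 51 and 4 reads and IFNE at 88 and 70. A loss of ligand thus cannot be told apart from an action further down, since the sum fell by less than the 2-fold set beforehand, interferon signalling itself raises IFNB1, and ligand protein was not measured. It may still account for the fall.

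The rise of glycolysis and hypoxia genes was not removed by the same comparison, with a median of 2.34 (1.6 to 2.74) relative to genes of like GC, length and level against 2.19 before. A shortage of usable iron in treated cells, which blocks the hydroxylases that degrade HIF proteins, may contribute, but it cannot be told apart from low oxygen. TFRC, whose messenger RNA is stabilised when iron is short, changed by 0.599 ± 0.0801 (edgeR adjusted p = 5.12e-05). That met the rise set beforehand for a shortage of iron, but low oxygen also raises TFRC. SLC11A2 (0.0843 ± 0.0673, adjusted p = 0.307) and CDC42BPA (0.163 ± 0.0811, adjusted p = 0.105), whose transcripts can carry an iron-responsive element of the same kind, were not called. Iron handling genes as a set rose in 6 of 13 tested members and fell in 3, and the set missed the threshold (camera adjusted p = 0.252). The set mixed genes of iron uptake and storage, which need not move together, and held HIF1A and EPAS1, the latter among the risers. Its miss therefore does not count against a shortage. Oxygen in the cultures, cell density and the medium were not recorded in the labels.

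The fall of metallothionein genes was not removed either, with a median of -3.29 (-4.59 to -1.99; 4 genes) relative to like genes against -3.26 before. Reads moving between paralogs are argued against, since the sum over all 21 metallothionein models fell from 978 to 55 CPM, a log2 ratio of -4.15 ± 0.106. A shortage of free zinc could lower these genes, and the zinc exporter SLC30A1 fell and the importer SLC39A10 rose by at least 2.15 on the log2 scale. The whole set of zinc transporters and MTF1 went both ways, with 6 of 17 tested members up and 6 down, and missed the threshold (camera adjusted p = 0.867). Camera asks for a shared direction, while a shortage would move exporters and importers apart, so the miss does not count against it. Of the other SLC39A importers, SLC39A13 (0.97 ± 0.0848), SLC39A8 (0.503 ± 0.105), SLC39A9 and SLC39A6 rose. SLC39A1, SLC39A3 (-0.425 ± 0.104) and SLC39A11 (-0.348 ± 0.108) fell. The shortage cannot be told apart from other causes, since SLC30A1 and SLC39A10 were seen before the test and metal levels were not measured.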
